A study of Homo sapiens with 26 samples.

How the data were processed

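Droplet-based single-cell RNA sequencing (10x Genomics Chromium, V3 chemistry for the 3′ ends of transcripts) was done on live CD4+ T cells sorted from blood mononuclear cells. The series holds 26 libraries, 1 per donor, from 10 healthy donors and 16 children with systemic lupus erythematosus (SLE). The deposited matrices hold unique molecular identifier (UMI) counts per gene and barcode, which the authors made with Cell Ranger on the GRCh38 build. These counts were neither normalised nor filtered by gene. Per the file headers, Cell Ranger 3.1.0 made 2 healthy and 2 SLE libraries, version 5.0.0 made 6 healthy and 10 SLE libraries, and version 6.0.0 made 2 healthy and 4 SLE libraries. The labels give no sequencing batch or date, so these versions were treated as the only known technical groups.

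The matrices of version 3.1.0 list 33538 genes and the others 36601. The 32732 gene identifiers on both lists were kept, and 98 of these were left out as sex-linked. All of the 32634 remaining genes had a position in GENCODE 29, and 1156 of them carry another symbol there. Coordinates below are on GRCh38, from GENCODE 29, and symbols are those of the deposited lists.

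The files hold 277051 barcodes, from 4863 to 15002 per library, with 26.94 to 89.34 M UMIs (M, mega) per library. Barcodes with fewer than 500 genes (12357), with more than 10% mitochondrial UMIs (30159) or with more than 6000 genes (18) were removed, and a barcode could fail more than 1 limit. The 245671 cells kept numbered 4289 to 14085 per library. Doublets were scored per library by the Scrublet scheme, as the share of simulated doublets among a cell's neighbours. The expected rate grew in proportion to the barcodes of a library, and a share of 0.5 of the expected number was called, highest scores first. This removed 11024 cells, 4.49% of those kept, with 1.94% to 6.00% per library. Median UMIs of called doublets were 1.47 to 2.06 times those of the other cells.

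Cells were embedded with 2000 variable genes and 30 principal components, aligned across libraries by the Harmony scheme, and clustered with the Leiden algorithm at resolution 1.2. Up to 2500 cells per library were clustered on a graph of 20 neighbours, and each other cell took the majority of its 15 nearest clustered cells. Genes of the interferon and immediate-early lists and the variable genes of T-cell receptors and immunoglobulins were kept out of the clustering genes. Clusters led by cytotoxic or other-lineage genes were clustered once more on their own. The resulting 29 clusters were named with marker lists fixed before the data were examined. A cluster took the class with the most markers among its 10 leading genes. It also needed 1 leading marker of its best list and 3 markers of the class (for other lineages, of that list) at 10 CPM or more and raised by over 0.25 on the log2 scale. Of the 29, 26 met this. Inside its class a cluster took the list with the most leading genes, and at a tie the list with more raised markers. The exception was 1 memory-like cluster with fewer than 3 raised markers of that list, which has a class only. Clusters of B cells (97 cells) and monocytes or dendritic cells (898 cells) were left out, and 233652 CD4+ T cells remained.

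Classes are called naive-like (5 clusters), memory-like (5 clusters, including those led by helper lists), regulatory-like (2 clusters), cytotoxic-like (6 clusters) and proliferating-like (1 cluster). Another 3 clusters with 8206 cells did not meet the rule, took no name and count among the CD4+ T cells only. These names rest on RNA alone, since no surface protein was measured.

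UMI counts were summed per donor over all CD4+ T cells and over each class, so that the donor was the replicate. A donor with fewer than 20 cells of a class was left out of that class, which left 9 healthy and 15 SLE donors in the cytotoxic-like class. Differences between SLE and healthy donors were tested with edgeR 4.0.16 (quasi-likelihood test, robust, TMM scaling, filterByExpr with a minimum count of 10). The length of the gene list, which separates Cell Ranger 3.1.0 from the later versions, was a covariate. A gene was called when its Benjamini-Hochberg adjusted p was under 0.05, and standard errors (SE) are those of the log2 fold change. Levels are CPM (counts per mega-count), given as the mean ± SD over donors, and those of tested genes are on TMM library sizes. The interferon level, the CD4, CD8A, CD8B and LYZ levels of cytotoxic-like cells and the gain of monocyte genes use total counts without TMM. Whether the effect of SLE differed between 2 classes was tested as the interaction of class and group, with the donor as a block.

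Shares of classes and the level of the interferon list per donor were compared by two-sided permutation tests with 100000 resamples, or by an exact permutation test where a group held fewer than 10 donors. The shares were adjusted over 5 classes. The interferon level is the mean of log2(CPM + 1) over the list, and 0.25 replaced the pseudocount of 1 as an alternative.

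The 31 gene lists, fixed before the data were examined, cover T-cell states, signalling, metabolism, stress and markers of other blood cells. They were tested with camera (limma 3.58.1) at a preset correlation of 0.01 between genes, again with an estimated correlation, and with fry. Where a list's count is "adjusted over the list alone", the adjustment ran over its members only. Named genes follow a rule fixed before the data were examined. It takes the 10 largest increases and 10 largest decreases among called genes with a mean of at least 10 CPM in all CD4+ T cells (5 and 5 in each class), and up to 4 called members per list with the smallest p. For a list with no called member, it takes the 2 members with the highest mean CPM. It adds FOXP3, IL2RA, CTLA4, IKZF2 and TIGIT in regulatory-like cells and the 5 smallest p in each direction of an interaction. Receptor genes, HLA genes outside a fixed list, GSTM1 and genes named only by a clone were not named, and 1 named gene is not reported here.

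The procedure was tested on simulated counts with the depth of the libraries and a dispersion read from its trend over expression. Known folds were put into the SLE group. Genes were drawn independently of each other, so recovery in the real data may be lower. In all CD4+ T cells, 58.2% of genes changed 1.5-fold, 83.6% of those changed 2-fold and 98.5% of those changed 4-fold were recovered. In regulatory-like cells these shares were 65.7%, 97.0% and 100%, and in cytotoxic-like cells 34.3%, 97.0% and 100%. Unchanged genes called numbered 3 in all CD4+ T cells, 10 in regulatory-like and 4 in cytotoxic-like cells. No 2 libraries of a group agreed within sampling noise among 165 pairs.

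Alternatives included RLE scaling, DESeq2 1.42.0, no filter on low counts, no covariate, 22 libraries of the longer gene list, the replicate number as a block, a stricter cell filter (800 genes, 5% mitochondrial UMIs), doublets kept, other clusterings, and each library left out in turn. Computation used R 4.3.3, Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and igraph 0.11.9, with matplotlib 3.10.9 for figures. No column of values in the files was left unused.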

Results

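The data are UMI counts of CD4+ T cells sorted from blood, in 26 libraries of 1 donor each: 10 healthy donors and 16 children with SLE, an autoimmune disease in which type I interferon genes are commonly raised in blood. After filtering, the CD4+ T cells of a donor carried 25.18 to 78 M UMIs (M, mega), with 53.0 ± 15.1 M in healthy donors (SD, n = 10) and 59.8 ± 13.2 M in SLE donors (n = 16). The comparison of SLE with healthy donors was made over all CD4+ T cells, within each class of cells, between classes, and for the shares of the classes. The title of the series names helper and regulatory clusters, and the regulatory-like class therefore has its own account.

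The first question was which kinds of CD4+ T cells the donors carried. Naive-like cells made up 59.4% ± 8.95 of the CD4+ T cells in healthy donors (SD, n = 10) and 43.9% ± 15.6 in SLE donors (n = 16), and 13 of 16 SLE donors lay below the healthy median. Regulatory-like cells made up 7.62% ± 1.56 in healthy and 13.01% ± 6.86 in SLE donors, and 12 of 16 SLE donors lay above the healthy median. Proliferating-like cells, led by the cell-cycle genes MKI67, TYMS and TOP2A, made up 1.475% ± 0.334 and 2.76% ± 1.51. Memory-like cells held 27.2% ± 8.90 and 34.5% ± 10.6, and cytotoxic-like cells 1.34% ± 1.15 and 1.79% ± 2.08, and neither difference passed the test.

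Naive-like clusters were led by FHIT, NOG, LRRN3, IGF1R, BACH2 or SOX4. Memory-like clusters were led by LMNA, LGALS1, GATA3 and PTGDR2, by CXCR5 and MAF, by CCR6 and KLRB1, by GZMK and CCL5, or, with 1 memory marker among its leading genes, by PASK, KLRB1 and TRADD (10978 cells). In the first, the memory and type 2 helper lists tied at 2 leading genes, and more raised markers gave it the memory name. The GZMK cluster (10685 cells), with GZMA and GNLY also leading, had 6 leading markers of the memory-like and 5 of the cytotoxic-like class. With genes called within a class left out of clustering, a cluster of 2581 cells led by GZMK, GZMA and CCL5 was named cytotoxic. The line between these classes was therefore narrow. Both regulatory-like clusters were led by FOXP3, the transcription factor of regulatory T cells, with TIGIT and FCRL3 in the larger (20144 cells) and DUSP4, HPGD and HLA-DRB1 in the smaller (5737 cells). Cytotoxic-like clusters were led by NKG7, GNLY and GZMH. This last class carried CD4 at 121.7 ± 36.1 CPM (SD, n = 24) but also CD8A at 36.6 ± 58.1 CPM and CD8B at 27.1 ± 44.6 CPM, and its mean of the monocyte gene LYZ was 336.8 ± 1646 CPM with a median of 0 CPM.

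The naive-like share fell by 15.5 percentage points (permutation p = 0.00896, adjusted over 5 classes 0.0224) and the regulatory-like share rose by 5.39 points (p = 0.0179, adjusted 0.0298). The proliferating-like share rose by 1.29 points (p = 0.00815, adjusted 0.0224). For memory-like cells the difference was 7.27 points (p = 0.0832, adjusted 0.104) and for cytotoxic-like cells 0.444 points (p = 0.645). Within the libraries of Cell Ranger 5.0.0 (6 against 10 donors) the differences were -15.9 points for naive-like cells (exact permutation p = 0.0391), 8.36 for memory-like, 6.16 for regulatory-like (exact permutation p = 0.0875), 0.0107 for cytotoxic-like and 0.824 for proliferating-like cells (exact permutation p = 0.0159). Within version 3.1.0 (2 against 2) they were -15.2, 9.02, 5.14, 0.502 and 0.354 points in the same order, and within version 6.0.0 (2 against 4) -14.1, 3.45, 3.64, 1.19 and 2.95 points.

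Some genes that lead these clusters also differed between the groups within their class: NOG, CLDN5 and MYB among 40 leading genes of naive-like clusters, BHLHE40, NPDC1 and the interferon gene IFI27 among 44 of memory-like clusters, and FOXP3, TIGIT, FCRL3, HDAC9 and TLR5 among 18 of regulatory-like clusters. None of 18 in cytotoxic-like clusters did. When the 1226 genes called within any class were kept out of the clustering, the naive-like share differed by -12.6 points (adjusted p = 0.0409) and the regulatory-like share by 4.39 points (adjusted p = 0.0409), but the proliferating-like difference was 0.295 points (adjusted p = 0.397). The naive-like call was lost with the replicate number as a block, as given below. It was also lost in the 22 libraries of the longer gene list (-15.8 points, adjusted p = 0.0566), within Cell Ranger 5.0.0 after adjustment (adjusted p = 0.0977) and without the 3 libraries that lost over 20% of barcodes to the mitochondrial limit (adjusted p = 0.0569). The proliferating-like call was lost in the same 3 settings (adjusted p = 0.0566, 0.0793 and 0.0569), with the stricter cell filter (adjusted p = 0.0564) and with interferon genes kept in clustering (0.725 points, adjusted p = 0.1105). The regulatory-like call was lost in the 22 libraries (5.39 points, adjusted p = 0.0832), within Cell Ranger 5.0.0 after adjustment (6.16 points, adjusted p = 0.122), without these 3 libraries (5.14 points, adjusted p = 0.0830) and without healthy replicate 2 (5.19 points, adjusted p = 0.0508).

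**Figure D1:**
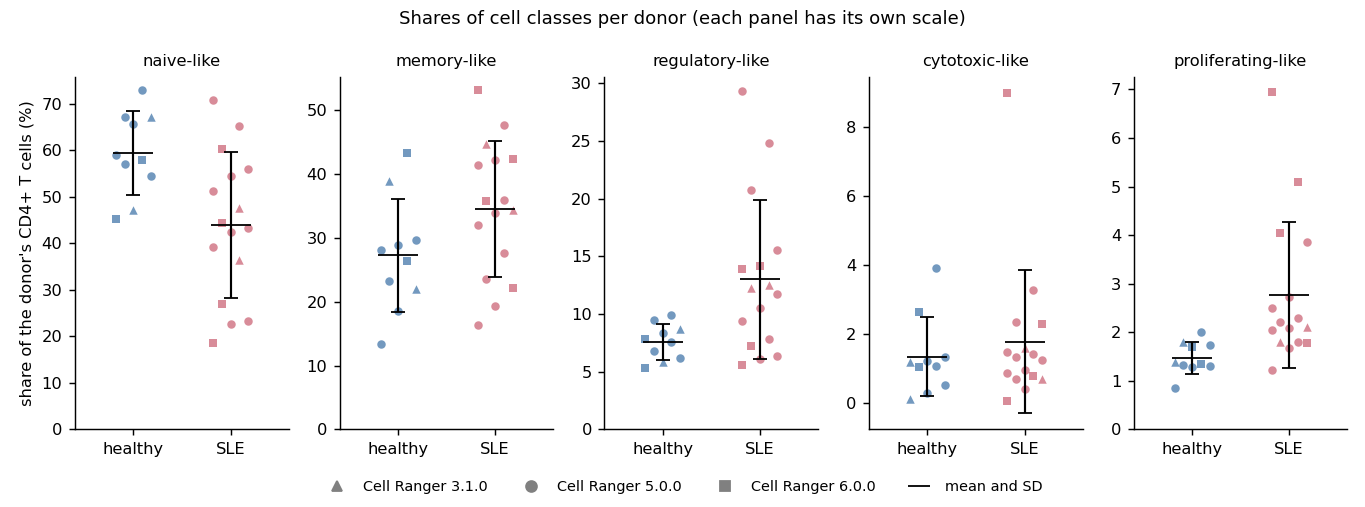
Share of each class among the CD4+ T cells of a donor, in percent, for 10 healthy (blue) and 16 SLE (red) donors, with 1 point per donor, marker shapes for the Cell Ranger version, and black bars for the mean and SD. Naive-like shares averaged 59.4% in healthy and 43.9% in SLE donors, and regulatory-like shares 7.62% and 13.01%.

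Across all CD4+ T cells, genes induced by type I interferon rose together in SLE. The mean level of the interferon list was 4.71 ± 0.158 in healthy donors (log2 of CPM + 1, SD, n = 10) and 5.78 ± 0.713 in SLE donors (n = 16), and 14 of 16 SLE donors lay above the highest healthy donor. The difference of 1.07 had a permutation p of 0.0002. Within Cell Ranger 5.0.0 it was 0.814 (exact permutation p = 0.0157), within version 3.1.0 it was 1.64 (2 against 2 donors, exact permutation p = 0.333) and within version 6.0.0 it was 1.42 (2 against 4 donors, exact permutation p = 0.133). The last 2 comparisons could not reach p under 0.05 at their size. The difference was 0.995 in naive-like, 0.962 in memory-like, 1.12 in regulatory-like and 1.19 in cytotoxic-like cells. In all CD4+ T cells, the 2 SLE donors not above every healthy donor were SLE replicates 3 (4.37) and 10 (4.81), both of Cell Ranger 5.0.0. Replicate 3 lay below the lowest healthy donor (4.45).

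**Figure D2:**
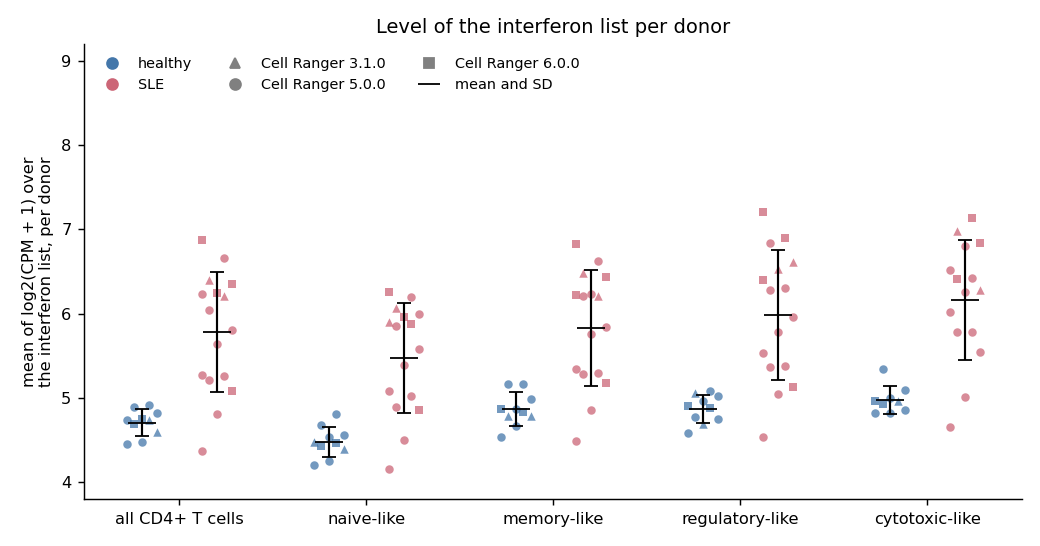
Mean of log2(CPM + 1) over the interferon list per donor, in all CD4+ T cells and in each class, for healthy (blue) and SLE (red) donors, with marker shapes for the Cell Ranger version and black bars for the mean and SD. In all CD4+ T cells the healthy donors averaged 4.71 and the SLE donors 5.78, and 14 of 16 SLE donors lay above every healthy donor.

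The whole-population comparison asked which transcripts differed between SLE and healthy CD4+ T cells. Of 15346 genes tested, 1331 were called, 890 higher and 441 lower in SLE (edgeR). IFI27, an interferon-induced gene (ENSG00000165949, chromosome 14, 94104836 to 94116698), rose by 5.38 on the log2 scale (SE 0.81, adjusted p = 0.000639), from 2.71 ± 1.46 CPM in healthy donors (SD, n = 10) to 108.9 ± 135 CPM in SLE donors (n = 16), and was higher in 15 of 16. IFIT3, whose family binds viral RNA (ENSG00000119917, chromosome 10, 89327894 to 89340971), rose by 3.51 (SE 0.64). IFI44L (ENSG00000137959, chromosome 1, 78619922 to 78646145) rose by 3.35 (SE 0.59), from 19.9 ± 12.7 to 208.6 ± 163 CPM. The antiviral genes OAS1, RSAD2, IFIT1 and CMPK2 rose by 2.83, 2.79, 2.77 and 2.42, SPATS2L by 2.53, and USP18, a brake on interferon signalling, by 2.29. MT1E, a metal-binding metallothionein, rose by 2.60, and its relative MT2A by 1.63, from 65.7 ± 17.8 to 203.1 ± 92.1 CPM in 16 of 16 donors.

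NOG had the largest decrease among the named genes of all CD4+ T cells. This gene, which encodes the BMP antagonist noggin (ENSG00000183691, chromosome 17, 56593699 to 56595590), fell by 1.64 on the log2 scale (SE 0.30, adjusted p = 0.00274), from 29.9 ± 12.3 CPM in healthy donors (n = 10) to 9.62 ± 5.86 CPM in SLE donors (n = 16), and all 16 SLE donors lay below the healthy median. SLC16A10, an amino acid transporter, fell by 1.06 and AFF3 by 1.05. MDS2 fell by 0.98, PECAM1, an adhesion molecule of naive T cells, by 0.94, CDCA7L by 0.84, CCDC141 by 0.79, USP53 by 0.76 and RALGPS2 by 0.73. These 9 calls held without any single library, whereas that of LRRN3, the remaining decrease of the 10, did not without 17 of the 26 libraries. Single healthy donors lay apart for IFIT1 (7.85 CPM, the next 4.43 CPM) and SLC16A10 (35.7 CPM, the next 21.9 CPM).

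Grouped by list, 73 of 82 measured interferon genes rose and none fell, and 80 were called when adjusted over the list alone. Their median log2 difference was 0.87 (camera adjusted p = 1.06e-45, but adjusted p = 0.178 with an estimated correlation). Besides those above, EPSTI1 rose by 2.24, the ISG15 ligase HERC5 by 2.08 and LY6E by 1.21. Of 20 naive-cell genes, 6 fell and none rose (median -0.34, camera adjusted p = 6.03e-08, adjusted p = 0.208 with an estimated correlation), among them PECAM1. Of 20 memory genes, 9 rose (median 0.58, camera adjusted p = 6.11e-09, adjusted p = 0.264 with an estimated correlation), among them the calcium-binding S100A6 by 0.49 and the transcription factor KLF6 by 0.94. Of 31 regulatory genes, 13 rose (median 0.78, camera adjusted p = 4.52e-09, adjusted p = 0.208 with an estimated correlation), among them the co-stimulatory receptor TNFRSF4 by 1.46, BATF by 0.78, CARD16 by 0.64 and IKZF4 by 1.09. Of 17 effector regulatory genes, 9 rose (median 0.99, camera adjusted p = 9.67e-08, adjusted p = 0.208 with an estimated correlation), among them TNFRSF18 by 1.32, the transcription factor PRDM1 by 1.17 and the inhibitory receptor TIGIT by 1.17. These lists moved while the regulatory-like share was 13.01% in SLE and 7.62% in healthy donors, and the naive-like share 43.9% and 59.4%. Members of the naive and memory lists were also called within classes: in regulatory-like cells 8 of 20 naive genes fell and 12 of 20 memory genes rose, in naive-like cells 1 fell and 5 rose, and in memory-like cells 2 fell and 2 rose. In naive-like cells 18 of 20 naive genes had a lower estimate, and in cytotoxic-like cells no member of these 2 lists was called by edgeR (9 and 19 tested). How much of the list changes the shares account for was left open.

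Over all CD4+ T cells, helper and activation genes rose in part. Of 19 follicular and peripheral helper genes, 6 rose (camera adjusted p = 0.0327, adjusted p = 0.498 with an estimated correlation), among them the inhibitory receptor PDCD1 by 1.69, the cytokine gene IL21 by 2.42 from a very low level (0.104 ± 0.0749 to 0.614 ± 0.624 CPM) and MAF by 0.81. Of 12 genes of interleukin-10-producing helper cells, 5 rose (camera adjusted p = 0.00135, adjusted p = 0.38 with an estimated correlation), among them LAG3 by 1.66. In memory-like cells, which hold the helper clusters, edgeR called 0 of 18 follicular helper genes (10 higher, 8 lower, median 0.07). It called 0 of 10 interleukin-10 helper genes there. In naive-like cells 3 of 15 and 3 of 8 rose. In the follicular helper cluster alone MAF was called (0.52, edgeR adjusted p = 0.038), and PDCD1 (1.35, adjusted p = 0.0864), CXCR5 and ICOS were not. How much of these rises the class shares account for was left open. Of 21 genes of the NF-kB response, 10 rose (camera adjusted p = 2.52e-07, adjusted p = 0.178 with an estimated correlation), with NFKB1 at 0.39, BIRC3 at 0.90, LTA at 0.76 and BCL3 at 1.36. Of 22 apoptosis and p53 genes, 5 rose (camera adjusted p = 1.76e-05, adjusted p = 0.178 with an estimated correlation), including the death receptor FAS by 1.10 and the survival gene BCL2 by 0.65. Single healthy donors lay apart for BIRC3 (55.3 CPM, the next 74.7 CPM), BCL3 (9.06 and 5.54 CPM) and FAS (5.40 and 9.65 CPM).

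Lists of proliferation, metabolism and stress had some members called. Of 30 proliferation genes, 5 rose (median 1.504, camera adjusted p = 3.31e-05, adjusted p = 0.587 with an estimated correlation), and 21 were called when adjusted over the list alone. The proliferating-like share was 2.76% in SLE and 1.475% in healthy donors, and this class was itself led by genes of the list. Of 20 glycolysis genes, 6 rose (camera adjusted p = 0.000189, adjusted p = 0.264 with an estimated correlation), including LDHA by 0.55 and PGAM1 by 0.37. Of 21 unfolded-protein genes, 4 rose (camera adjusted p = 0.00127, adjusted p = 0.316 with an estimated correlation). Of 59 oxidative phosphorylation genes of the nucleus, 4 rose and 2 fell (camera adjusted p = 0.00138, adjusted p = 0.654 with an estimated correlation), and ATP5F1A fell by 0.24. Of the 13 mitochondrially encoded genes, 3 fell and none rose (median -0.35, camera adjusted p = 2.71e-05, adjusted p = 0.316 with an estimated correlation), and MT-CO3, a subunit of cytochrome c oxidase, fell by 0.59 (SE 0.14) from 7121 ± 2067 to 4598 ± 1167 CPM. Beside this, the median mitochondrial share per barcode was 4.65% ± 1.67 in healthy donors (SD, n = 10) and 3.36% ± 0.905 in SLE donors (n = 16), with permutation p = 0.0157 and adjusted p = 0.103 over 10 quality measures, and the median number of genes per barcode was 1537 ± 153 and 1732 ± 221 (adjusted p = 0.103).

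Of the other lists, the dendritic one alone was called. Members called were 2 of 14 for type 1 helper (IL12RB2 among them), 0 of 8 for type 2 helper, 0 of 13 for type 17 helper, 1 of 24 for cytotoxic, 4 of 10 for inhibitory receptors (3 higher, 1 lower). They were 2 of 27 for immediate-early, 1 of 18 for heat shock (DNAJA1), 2 of 23 for glucocorticoid response (MT1E, MT2A), 1 of 29 for T-cell receptor signalling (PTPN22) and 4 of 24 for trafficking genes. In type 2 helper genes GATA3 stood at 0.21 (adjusted p = 0.328) and IL4R at -0.06 (adjusted p = 0.817), and in type 17 helper genes RORA at 0.28 (adjusted p = 0.276) and KLRB1 at -0.03 (adjusted p = 0.965). Of markers of other blood cells, 1 of 11 monocyte genes (CTSS, 0.43), 1 of 8 B-cell genes (MZB1, 1.24), 0 of 9 natural killer genes and 0 of 3 platelet genes rose. In turn, 1 of 8 genes of CD8 and gamma-delta T cells and 1 of 4 dendritic genes fell. The single erythroid gene tested, SLC4A1, stood at 0.08 (adjusted p = 0.917). The dendritic list passed camera (adjusted p = 0.0152, adjusted p = 0.178 with an estimated correlation). For T-cell receptor signalling the median was -0.00043, the mean 0.0058 and the camera direction lower.

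Of the 31 lists, 30 had enough members for a test; 15 were called at the preset correlation, 12 higher and 3 lower, and 0 with an estimated correlation (camera). Fry called 12. The 1331 genes numbered 588 in the 22 libraries of the longer gene list and 487 without healthy replicates 5 and 9 and SLE replicate 15, which each lost over 20% of barcodes to the mitochondrial limit. In the 16 libraries of Cell Ranger 5.0.0 edgeR called 0 genes (2331 at an unadjusted p under 0.05). DESeq2 called 2026 over all libraries, and the edgeR count was 740 without healthy replicate 5 and 825 without healthy replicate 7.

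**Figure D3:**
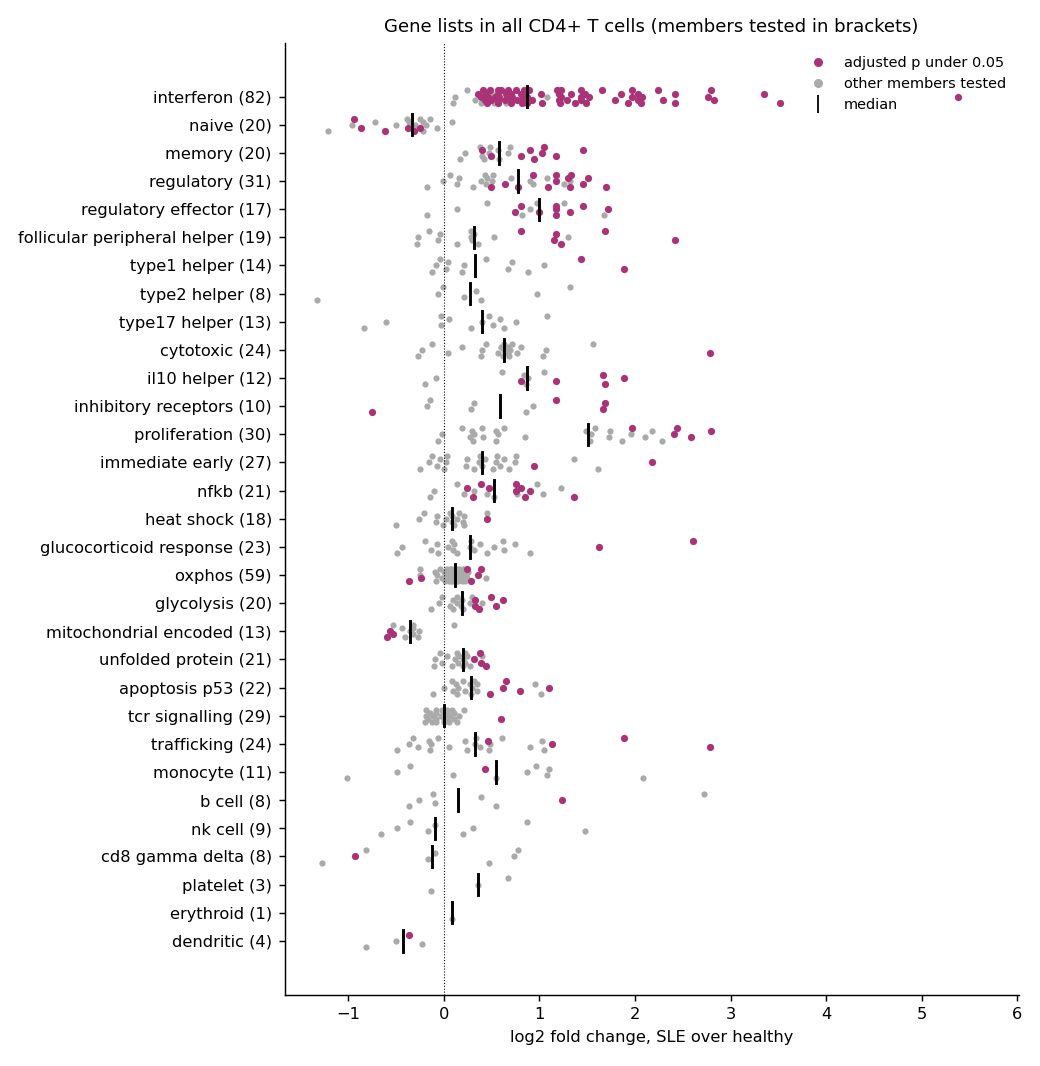
Log2 fold change of SLE over healthy donors for each tested member of the 31 gene lists in all CD4+ T cells, with members past an adjusted p of 0.05 in purple, others in grey and the list median as a black line. In the interferon list 73 of 82 members were called, all higher, with a median of 0.87.

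Naive-like cells, named by their RNA, were compared first among the classes. Of 13580 genes, 550 were called, 378 higher and 172 lower in SLE, and 63 of 82 interferon genes rose. IFI27 rose by 6.52 (SE 1.11) from 0.312 ± 0.315 CPM in healthy donors (SD, n = 10) to 30.8 ± 46.9 CPM in SLE donors (n = 16), IFIT3 by 3.74, IFI44L by 3.58 and OAS1 by 2.88. PRDM1, a transcription factor of effector cells, rose by 3.00 (SE 0.64) from 2.08 ± 1.15 to 17.3 ± 25.2 CPM, with 1 healthy donor apart at 4.65 CPM (the next 2.82 CPM). NOG fell by 1.12 (SE 0.23), USP53 by 0.86 and SLC16A10 by 0.72. Of 21 NF-kB genes 8 rose, of 21 apoptosis and p53 genes 5 rose, of 24 regulatory genes 8 rose, of 20 memory genes 5 rose, of 20 naive genes 1 fell and of 13 mitochondrially encoded genes 3 fell. The count was 209 in the 22 libraries of the longer list, 228 without the 3 libraries of high mitochondrial loss, 5 in the Cell Ranger 5.0.0 libraries, 940 with DESeq2 and 342 without healthy replicate 7.

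Memory-like cells, which include the helper clusters, were compared in the same way. Of 12953 genes, 342 were called, 222 higher and 120 lower in SLE, and 53 of 82 interferon genes rose. IFI27 rose by 4.47 (SE 0.72) from 7.28 ± 4.56 CPM in healthy donors (SD, n = 10) to 155.7 ± 166 CPM in SLE donors (n = 16), IFIT3 by 3.18, IFIT1 by 2.96, IFI44L by 2.91 and RSAD2 by 2.90. NCF1, a subunit of the phagocyte oxidase, fell by 0.71 (SE 0.17) from 46.9 ± 6.17 to 29.7 ± 11.9 CPM, and FAM117B by 0.75. Of 21 NF-kB genes 4 rose, of 26 regulatory genes 4 rose, of 20 naive genes 2 fell and of 13 mitochondrially encoded genes 2 fell. The count was 56 in the 22 libraries of the longer list, 116 without the 3 libraries of high mitochondrial loss, 0 in the Cell Ranger 5.0.0 libraries (edgeR, 1128 at an unadjusted p under 0.05) and 624 with DESeq2 over all libraries. It was 203, 179, 172 and 216 without healthy replicates 1, 5, 7 and 10, and 202, 530 and 225 without SLE replicates 1, 3 and 5.

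Cytotoxic-like cells gave the smallest count, over 9 healthy and 15 SLE donors. Of 6275 genes, 59 were called by edgeR, 38 higher and 21 lower, and 26 of 76 interferon genes rose. IFI27 rose by 5.84 (SE 0.99), IFI44L by 4.22, IFIT3 by 3.94, USP18 by 3.03 and OAS1 by 2.80, with 1 healthy donor apart for OAS1 at 28.4 CPM (the next 16.6 CPM). NCR3, an activating receptor of natural killer cells, fell by 2.06 (SE 0.41), with 1 healthy donor apart at 178.8 CPM (the next 66.0 CPM), NSG1 by 1.53 and PLCB1 by 1.30. Of 13 mitochondrially encoded genes 4 fell. The count was 0 with the stricter cell filter (edgeR, 6 against 15 donors, 487 at an unadjusted p under 0.05) and in the Cell Ranger 5.0.0 libraries (407 unadjusted), 33 in the 22 libraries of the longer list, 15 without the 3 libraries of high mitochondrial loss and 143 with DESeq2. Without healthy replicates 2, 3, 4, 5, 6, 8, 9 and 10 it was 28, 110, 32, 93, 33, 29, 23 and 35, and without SLE replicates 3, 5, 8, 10 and 12 it was 127, 39, 37, 96 and 91.

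The regulatory-like comparison asked how SLE regulatory cells differed from healthy ones. Of 10622 genes, 850 were called, 501 higher and 349 lower in SLE, and 73 of 82 interferon genes rose (median 0.93, camera adjusted p = 3.14e-48, adjusted p = 0.183 with an estimated correlation). FOXP3 (ENSG00000049768, chromosome X, 49250436 to 49264826) rose by 0.58 (SE 0.14, adjusted p = 0.0141), from 65.5 ± 7.76 CPM in healthy donors (SD, n = 10) to 97.5 ± 28.3 CPM in SLE donors (n = 16), and was higher in 13 of 16. Of 20 naive genes 8 fell and of 20 memory genes 12 rose, though neither list was called with an estimated correlation (adjusted p = 0.183 and p = 0.225). The homing receptor CCR7 fell by 0.64 (SE 0.15), PECAM1 by 1.73 and BACH2, a repressor of effector genes, by 0.96, whereas S100A4 rose by 0.77 and S100A11 by 1.19. PDCD1, which encodes the inhibitory receptor PD-1, rose by 1.94 (SE 0.42), from 3.61 ± 1.38 to 13.8 ± 9.88 CPM, in 16 of 16 donors.

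Of the other identity genes of regulatory cells, TIGIT rose by 0.69 (SE 0.20, adjusted p = 0.0368). IL2RA, the interleukin-2 receptor alpha chain, stood at -0.05 (SE 0.22, adjusted p = 0.94), CTLA4 at -0.52 (SE 0.24, adjusted p = 0.191) and IKZF2 at 0.14 (SE 0.13, adjusted p = 0.579). The largest increases were IFI27 (6.10, SE 1.01), IFI44L (3.96), RSAD2 (3.67), IGFL2 (3.23) and IFIT3 (3.17), with 1 healthy donor apart for IFI27 at 11.4 CPM (the next 4.63 CPM). The largest decreases were FXYD2 (-2.25, SE 0.47), a regulator of the sodium pump, NOG (-2.17), the growth factor receptor IGF1R (-1.59), FCER1G (-1.32) and MAN1C1 (-1.29). The call of TIGIT was lost without healthy replicate 2, 3, 4, 5, 7 or 10 or SLE replicate 1, 4, 5, 14 or 16 (log2 0.627 to 0.7005, adjusted p up to 0.0778). The call of FCER1G was lost without healthy replicate 2, 3, 5, 7 or 10 or SLE replicate 1, 8, 13, 14 or 16 (adjusted p up to 0.113).

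By list, the naive genes had a median of -0.58 (camera adjusted p = 5.03e-08, adjusted p = 0.183 with an estimated correlation), and NOSIP fell by 0.58 and LDHB by 0.37. The memory genes had a median of 0.55 (camera adjusted p = 2.27e-10, adjusted p = 0.225 with an estimated correlation). Of 30 regulatory genes 8 rose (camera adjusted p = 0.000589, adjusted p = 0.346 with an estimated correlation), with TNFRSF4 at 1.21, CARD16 at 0.59 and BATF at 0.71. Of 17 effector regulatory genes 5 rose (camera adjusted p = 7.56e-05, adjusted p = 0.32 with an estimated correlation). Of 8 inhibitory receptors 5 rose (camera adjusted p = 0.00238, adjusted p = 0.183 with an estimated correlation), BTLA by 0.99 and TOX, counted with them as their regulator, by 0.59. Of 16 follicular helper genes 7 rose (camera adjusted p = 0.0082, adjusted p = 0.314 with an estimated correlation), CD200 by 1.09 among them. Trafficking genes were not called as a list, but the integrin ITGA4 rose from 127 ± 43.7 to 258.8 ± 99.5 CPM, the gut-homing receptor GPR15 by 1.89, and CCR7 fell. Of 21 apoptosis and p53 genes 4 rose (camera adjusted p = 0.000442, adjusted p = 0.183 with an estimated correlation), with CASP1 at 0.81, FAS at 0.82 and BCL2 at 0.54.

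Further lists called in regulatory-like cells were NF-kB (3 of 20 rose, adjusted p = 0.00437, 0.314 with an estimated correlation), interleukin-10 helper (2 of 8, 0.0133 and p = 0.32), glycolysis (4 of 19, 0.00292 and p = 0.314) and oxidative phosphorylation (7 of 59 rose and 2 fell, 0.000196 and p = 0.50). Of 13 mitochondrially encoded genes 1 fell (MT-CO3 by 0.58, adjusted p = 6.56e-05 for the list, 0.32 with an estimated correlation), beside the lower mitochondrial share per barcode in SLE given above. Lists not called there had 2 of 9 type 1 helper (1 higher, 1 lower), 0 of 3 type 2 helper, 0 of 7 type 17 helper, 2 of 13 cytotoxic (1 higher, 1 lower) genes called. Called there too were 0 of 16 proliferation, 1 of 23 immediate-early, 0 of 17 heat shock, 2 of 21 glucocorticoid response, 0 of 21 unfolded-protein and 2 of 29 T-cell receptor genes (1 higher, 1 lower). For trafficking it was 4 of 20. For the immediate-early and glucocorticoid lists the median was above 0 and the camera direction lower. Of other blood cells' markers, 1 of 4 monocyte, 1 of 3 B-cell, 1 of 3 natural killer and the single dendritic gene tested fell, and 0 of 2 CD8 and gamma-delta genes were called. In all, 13 of 28 lists were called, 11 higher and 2 lower, and 0 with an estimated correlation (camera), while fry called 12. The 850 genes numbered 438 in the 22 libraries of the longer list, 405 without the 3 libraries of high mitochondrial loss, 19 in the Cell Ranger 5.0.0 libraries, 553 without healthy replicate 5 and 517 without healthy replicate 7.

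**Figure D4:**
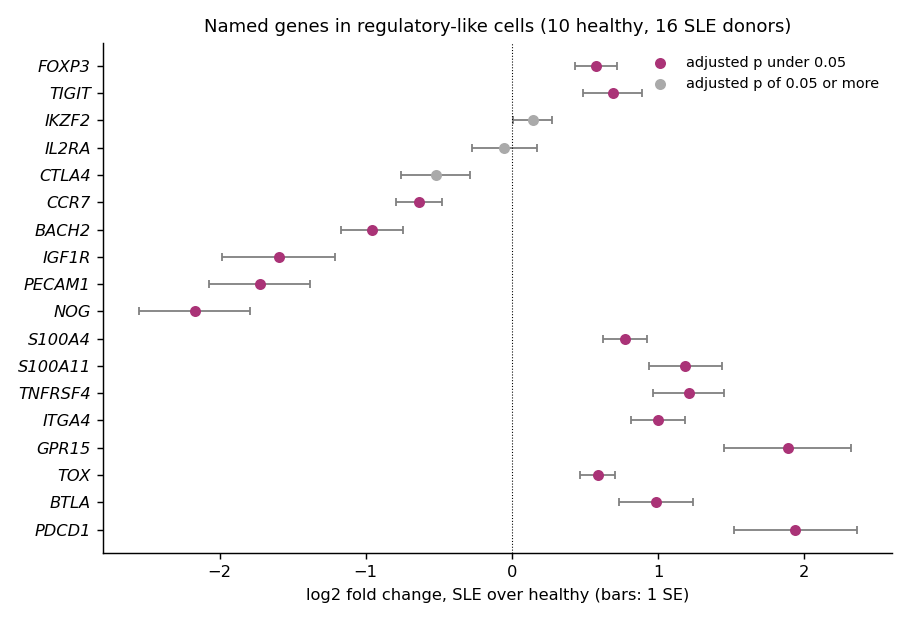
Log2 fold change of SLE over healthy donors in regulatory-like cells for 18 named genes, with bars of 1 SE, purple for an adjusted p under 0.05 and grey for others. FOXP3 (0.58) and TIGIT (0.69) lay above 0, IL2RA, CTLA4 and IKZF2 were not called, CCR7, BACH2, IGF1R, PECAM1 and NOG were lower and PDCD1 (1.94) was highest.

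The last comparison asked whether SLE acted differently on regulatory-like or memory-like cells than on naive-like cells of the same donors. Of 13153 genes, 217 differed in their SLE effect between regulatory-like and naive-like cells, 84 with the higher and 133 with the lower effect in regulatory-like cells. Immediate-early genes, which respond quickly to stimulation, had lower effects in regulatory-like cells for 26 of 27 members (median -0.51), 5 of them called (FOS -0.74, JUN -0.73, FOSB -0.88, EGR1 -1.60 and NR4A1 -1.48), and 18 were called when adjusted over the list alone, while none of the 5 was called within either class. In naive-like cells 21 of 25 members had a higher estimate in SLE (median 0.70, 1 called). In the larger and smaller regulatory-like clusters the list medians were 0.04 and -0.10. The lower effects thus came with higher estimates in naive-like cells rather than with a clear fall of the list in regulatory-like cells. NF-kB genes had lower effects for 19 of 21 members (median -0.30), 2 of them called, and naive genes for 15 of 20 (median -0.36), 3 of them called. In naive-like cells 18 of 21 NF-kB genes had a higher estimate in SLE (median 0.78). Follicular helper genes BTLA, CD200 and POU2AF1 had higher effects by 0.85, 1.45 and 1.42, and oxidative phosphorylation genes higher effects for 52 of 59 members (median 0.07), 3 of them called. Of 82 interferon genes 1 was called (median 0.09).

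The smallest p values belonged to LITAF (-0.36, SE 0.05), which fell in regulatory-like cells by 0.56, SORBS3 (-0.89), GTSCR1 (-2.05), HIST2H2BE (-1.12) and KRT1 (-2.58) with lower effects. On the other side they belonged to the endocytic adaptor EPS15 (0.42, SE 0.07), the ion exchanger SLC9A7 (1.13), CD4 (0.26), RFX7 (0.55) and COX6C (0.22) with higher effects. EPS15 rose in regulatory-like cells by 0.53 and stood at 0.10 in naive-like cells (adjusted p = 0.442). KRT1 had very low levels in regulatory-like cells (1.32 ± 1.52 to 0.189 ± 0.224 CPM) and no test within that class. The count of 217 became 60 in the 22 libraries of the longer list, 62 with the stricter cell filter, 45 without the 3 libraries of high mitochondrial loss and 0 in the Cell Ranger 5.0.0 libraries (edgeR, 1385 at an unadjusted p under 0.05). It was 124, 77, 86 and 127 without healthy replicates 4, 5, 7 and 10, and 395 and 380 without SLE replicates 3 and 9. Without the low-count filter 169 genes were called, 98 with the higher and 71 with the lower effect, so the direction of the majority turned.

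Between memory-like and naive-like cells 8 of 14078 genes differed, 1 with the higher and 7 with the lower effect in memory-like cells. N4BP1 had an effect higher by 0.28 (SE 0.05) in memory-like cells. The interferon-induced gene ODF3B rose by 3.84 in naive-like and by 1.83 in memory-like cells, a difference of -1.95 (SE 0.34, adjusted p = 0.0256), and SLFN12L (-0.38), PRPS2 (-0.44), H2AFX (-0.55) and SCAMP1-AS1 (-0.33) also had lower effects. ODF3B started from a very low level in naive-like cells (0.384 ± 0.211 to 5.74 ± 3.46 CPM) and a higher one in memory-like cells (3.59 ± 1.04 to 13.2 ± 6.61 CPM). This count was 21 with RLE scaling, 17 with the stricter cell filter and 0 by edgeR in the 22 libraries of the longer list, the Cell Ranger 5.0.0 libraries and those without high mitochondrial loss (1343, 957 and 1367 at an unadjusted p under 0.05). It was 3, 4, 5, 3 and 0 without healthy replicates 1, 3, 6, 9 and 10 (for the 0, 1416 at an unadjusted p under 0.05), and 14, 34, 13, 13, 36, 36, 38 and 16 without SLE replicates 1, 3, 6, 7, 9, 10, 12 and 16.

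**Figure D5:**
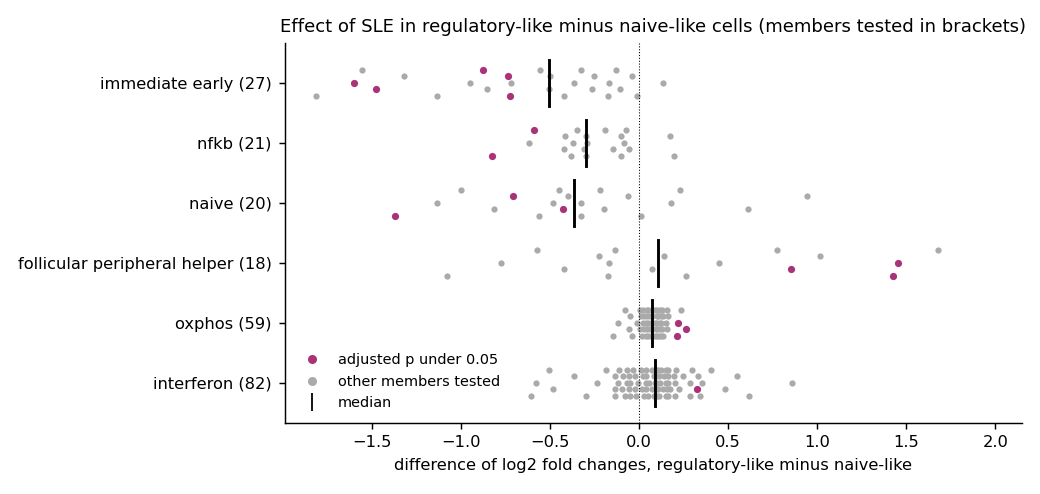
Difference of the log2 effect of SLE, regulatory-like minus naive-like cells, for tested members of 6 gene lists, with called members in purple and list medians as black lines. Immediate-early genes lay below 0 for 26 of 27 members, and oxidative phosphorylation genes above 0 for 52 of 59.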

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

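The restrictions to Cell Ranger 5.0.0 libraries and to libraries without high mitochondrial loss, and the model with the Cell Ranger version as covariate, were chosen after the data had been seen, as were the fits of single clusters and the other tests of explanations for the 3 patterns weighed. The interaction tests, the search for donors lying apart and the splits of the libraries were chosen before.

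Among genes whose SLE effect differed between regulatory-like and naive-like cells of the same donors, 217 passed the interaction test, and 8 did so between memory-like and naive-like cells. The endocytic adaptor EPS15 (0.422), the ion exchanger SLC9A7 (1.13), CD4 (0.2561), RFX7 (0.5474) and the cytochrome oxidase gene COX6C (0.2208) had higher log2 effects in regulatory-like cells. LITAF (-0.3577), SORBS3 (-0.8932), GTSCR1 (-2.055), HIST2H2BE (-1.124) and KRT1 (-2.582) had lower ones. Against naive-like cells, memory-like cells had the higher effect for N4BP1 (0.2814) and the lower effect for the interferon-induced gene ODF3B (-1.945), PRPS2 (-0.4402), SCAMP1-AS1 (-0.3311), the histone gene H2AFX (-0.5534) and SLFN12L (-0.3803). In 41 splits of the same libraries, the real one included, 1 reached 217 genes, and the highest other split gave 1. For the memory-like comparison 1 reached 8 genes, with 2 in the highest other. No other split reached either count, but so few splits cannot exclude chance. The split with the highest count in all CD4+ T cells, given below, was not among them. All 10 genes of the regulatory-like comparison kept their calls without any single library. Of the 6 named genes of the memory-like comparison, all lost theirs without healthy replicate 10 (0 genes called by edgeR, 1416 at an unadjusted p under 0.05), where N4BP1 had a log2 difference of 0.2645 and an adjusted p of 0.0744. ODF3B and H2AFX also lost theirs without healthy replicates 1, 3, 6 and 9, SLFN12L without 1, 6 and 9 and SCAMP1-AS1 without 1 and 3, where 3, 4, 5 and 3 genes were called without replicates 1, 3, 6 and 9.

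Single healthy donors lay apart from the others of their group in 19 of 205 groups tested (9.27%). Chance gives about 1 in 20 for independent, normally distributed values. Most groups here are untransformed CPM of the same donors, so these rates are not directly comparable. The number given for each group is the gap to the nearest donor over the range of the group. In all CD4+ T cells the highest donor lay apart for the interferon gene IFIT1 (0.5055), SLC16A10 (0.5518), the proliferation genes TK1 (0.48) and RRM2 (0.559), BCL3 (0.5452), PFKP (0.5735), FCER1G (0.4686), the erythroid gene SLC4A1 (0.791, 1.77 CPM against 0.442 CPM in the next) and ITM2C (0.4927), and the lowest for BIRC3 (0.4838) and FAS (0.4954). A donor also lay apart for PRDM1 in naive-like cells (0.4729), for IFIT1 (0.5782) and TTN (0.5833) in memory-like cells, for IFI27 (0.5933), ATP5F1A (0.4938) and HSP90B1 (0.534) in regulatory-like cells, and for OAS1 (0.5046) and NCR3 (0.6308) in cytotoxic-like cells.

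In all CD4+ T cells 73 of 82 interferon-induced genes were called higher in SLE, though the list was not called with an estimated correlation (adjusted p = 0.178). The Cell Ranger version is argued against by the 16 libraries of version 5.0.0, in which the median log2 difference of the 73 called genes was 0.7567, against 1.021 over all libraries, and 73 of 73 were positive. These libraries are among those in which the genes were called. The level of the whole list, fixed beforehand, also rose there (exact permutation test given above). RNA of monocytes is argued against as well, since LYZ, S100A8 and S100A9 together gained 63.87 CPM (SE 86.55) in SLE and the called interferon genes 4111 CPM (SE 779). Both gains are over all cells kept, monocyte clusters included, whereas the pattern is in CD4+ T cells without these clusters. With both explanations argued against, an effect of SLE on the CD4+ T cells may underlie the pattern, as a hypothesis found and tested on the same data. Other differences between the groups, such as treatment, were not recorded and stay open.

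In all CD4+ T cells 3 of 13 mitochondrially encoded genes were called lower in SLE, and the list was not called with an estimated correlation (adjusted p = 0.316). Libraries that lost many barcodes to the mitochondrial limit are argued against, since without the 3 of them the median log2 difference of the 13 genes was -0.3583, against -0.3549 over all libraries. The Cell Ranger version is argued against by -0.3658 in the version 5.0.0 libraries, where 13 of 13 genes were negative. Differences in how the blood was handled stay open, since no label gives them.

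In regulatory-like cells 8 of 20 naive genes were called lower and 12 of 20 memory genes higher in SLE, and neither list was called with an estimated correlation (adjusted p = 0.183 and p = 0.225). A shift between the clusters of the class may move such genes, but within the larger cluster alone the slope of the folds of the called genes on their folds in the whole class was 1.097 over 803 genes. In the smaller cluster it was 0.7686 over 655 genes, of which 649 kept their sign. Both slopes run over all called genes, not the 2 lists alone. The larger cluster holds 20144 of the 25881 cells in which the genes were called, so its slope is partly set by this overlap. Within the larger cluster 8 naive genes fell, 1 rose and 13 memory genes rose, and within the smaller 0 of 14 naive genes and 1 of 20 memory genes were called by edgeR. The Cell Ranger version is argued against by a slope of 0.9273 over 848 genes in the version 5.0.0 libraries. These libraries are among those in which the genes were called, so the overlap may raise this slope and the version is not excluded. A shift of cell states inside the larger cluster was not separated from a change within cells and stays open.

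For the counts of changed genes, 100 splits of the libraries into groups of the same sizes were drawn, the real one included. As many genes were called by 2 of them in all CD4+ T cells (real 1331, highest other 1489), 2 in naive-like cells (550 and 587), 2 in memory-like cells (342 and 992), 1 in regulatory-like cells (850 and 357) and 1 in cytotoxic-like cells (59 and 1). Each share is under 0.05, but the split with 1489, 587 and 992 genes was a single one that put 5 of the 6 libraries of Cell Ranger 6.0.0 into the group of 10. This make-up was noticed after the count was seen, and that split was not fitted with the version in the model, so that other structure among the donors stays open. Another split with 5 of these 6 libraries in that group gave 353 genes in all CD4+ T cells and 0 in naive-like cells. In all CD4+ T cells 1 split with 2 of them there gave 154 genes and 1 with 0 of them gave 116. The make-up alone therefore did not set the counts. For the real groups with the version as covariate, edgeR called 1670 genes in all CD4+ T cells, 633 in naive-like, 394 in memory-like, 964 in regulatory-like and 73 in cytotoxic-like cells, of which 1324, 548, 338, 848 and 59 were called in the model without it too.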

How the results depend on the processing

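The settings with the Cell Ranger 5.0.0 libraries alone, without the 3 libraries of high mitochondrial loss, with the Cell Ranger version as covariate, with that of the gene list by class, and with called genes left out of clustering were chosen after the data had been seen, and the others before. Of 174 calls of named genes within a class, 122 held without any single library, and no called gene changed sign under any setting. Of those with a value, 1 of 173 kept its call in the Cell Ranger 5.0.0 libraries, 97 of 174 without the 3 libraries, 114 of 173 in the 22 libraries, 141 of 174 without the low-count filter and 148 of 171 with the stricter cell filter. The interferon level in all CD4+ T cells kept its call under each alternative here (0.8144 to 1.166), but not within Cell Ranger 3.1.0 or 6.0.0 alone, where too few donors could reach the threshold.

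With DESeq2, 2026 genes were called in all CD4+ T cells, 940 in naive-like, 624 in memory-like and 143 in cytotoxic-like cells. In the 22 libraries of the longer gene list the counts were 588, 209, 56, 438 for regulatory-like and 33 for cytotoxic-like cells, with 60 for the regulatory-like and 0 for the memory-like interaction. Here the naive-like share differed by -15.75 points and the regulatory-like share by 5.387 (adjusted p = 0.05657 and 0.08323). In the 16 Cell Ranger 5.0.0 libraries edgeR called 0, 5, 0, 19 and 0 genes (2331, 1603, 1128, 1610 and 407 unadjusted) and 0 in both interactions (1385 and 957 unadjusted). Shares there differed by -15.86 and 6.162 points (adjusted p = 0.09771 and 0.1225). Without the 3 libraries of high mitochondrial loss the counts were 487, 228, 116, 405 and 15, with 45 and 0 for the interactions (1367 unadjusted for the latter), and the shares -15.57 and 5.136 (adjusted p = 0.0569 and 0.08303). Fewer donors entered these 3 restrictions, and the cause beyond that was not tested. Both SLE donors without a raised interferon level, replicates 3 and 10, are among the Cell Ranger 5.0.0 libraries. Leaving out SLE replicate 3 alone gave 1921 genes in all CD4+ T cells. With the stricter cell filter 227 memory-like and 0 cytotoxic-like genes were called (edgeR, 487 unadjusted, with 6 healthy donors left), 62 and 17 for the interactions, and the memory-like share differed by 9.699 points (adjusted p = 0.04593). The proliferating-like call was lost there (adjusted p = 0.0564), in the 22 libraries (0.05657), in the Cell Ranger 5.0.0 libraries (0.0793), without the 3 libraries (0.0569), with interferon genes kept in clustering (0.7249 points, adjusted p = 0.1105) and with called genes left out of it (0.2947 points, adjusted p = 0.397). With RLE scaling the memory-like interaction had 21 genes. Without the low-count filter the regulatory-like interaction had 169 genes, 98 higher and 71 lower, against 84 and 133 with the filter. With an estimated correlation camera called 0 lists in all CD4+ T cells and 0 in regulatory-like cells, whereas fry called 12 and 12. The cause was not tested in these cases.

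Replicate numbers were not taken to pair the donors, and a block on numbers 1 to 10 is therefore an alternative only. Donors of other numbers, all with SLE, were left out of it, so its results differ by fewer donors as well as by the block. With the block 83 of 169 named calls were kept, and the counts were 412 in all CD4+ T cells, 196 in memory-like, 474 in regulatory-like and 29 in cytotoxic-like cells. The naive-like share differed by -14.69 points (adjusted p = 0.1172). Signs changed with the block for IL4R (0.01241) and KLRB1 (0.1345) in all CD4+ T cells, for IL4R in regulatory-like cells (0.08408) and for the immediate-early list there (camera adjusted p = 0.0005007). The cause was not tested.

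Leaving out 1 library at a time, the counts ran from 740 to 1921 in all CD4+ T cells, 342 to 784 in naive-like, 172 to 530 in memory-like, 517 to 1099 in regulatory-like and 23 to 127 in cytotoxic-like cells, and from 77 to 395 and 0 to 38 for the interactions (1416 unadjusted at the 0). The libraries behind them are named in the report. The memory-like share ran from 5.735 to 9.055 points, with calls without healthy replicate 9 (9.055, adjusted p = 0.0419) and SLE replicate 9 (8.476, adjusted p = 0.0496). The regulatory-like share ran from 4.299 to 5.881, with its call lost without healthy replicate 2, and the cytotoxic-like share from -0.03528 (without SLE replicate 14) to 0.7319. Uncalled genes that changed sign without 1 library were KLRB1 (-0.1583 to 0.1081) and SLC4A1 (-0.07506 to 0.4106) in all CD4+ T cells, and IL4R (-0.08389 to 0.02031), HSP90B1 (-0.01888 to 0.05371) and IL2RA (-0.1881 to 0.001761) in regulatory-like cells.

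Other changes of sign were all in genes or lists without a call over all libraries: KLRB1 with the stricter filter (0.09437) and in Cell Ranger 5.0.0 libraries (0.2023), FCER1G with no cluster left out (0.8836), NRGN with the stricter filter (-0.03543), and SLC4A1 without the gene-list term (-0.126) and with the stricter filter (-0.00319). In regulatory-like cells they were GATA3 in Cell Ranger 5.0.0 libraries (0.0007261), IL4R without the low-count filter (0.0002991), in Cell Ranger 5.0.0 libraries (0.06247) and without the 3 libraries (0.01178), and IL2RA in the 22 libraries (0.01256). The immediate-early and glucocorticoid lists changed direction in the Cell Ranger 5.0.0 libraries (camera adjusted p = 0.008959 and 0.008959). The cause was not tested. In simulated counts at this depth, 58.2% of 1.5-fold, 83.6% of 2-fold and 98.5% of 4-fold changes were called in all CD4+ T cells, and 34.3%, 97.0% and 100% in cytotoxic-like cells. For the regulatory-like interaction these shares were 59.7%, 79.1% and 98.5%. The simulation did not vary depth alone, and it drew genes independently of each other.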

Other observations

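The fits of single clusters and the tests of cluster shares were chosen after the data had been seen.

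With all 26 libraries, interferon genes were called in each helper cluster and in the proliferating cluster, but few or none remained in 4 of these 5 clusters with 22 libraries. The cluster named follicular helper by CXCR5 and MAF had 307 called genes, 216 higher and 91 lower in SLE, with 58 interferon genes among them. The type 1 helper cluster, led by GZMK, CCL5, GZMA and GNLY, had 90 (71 higher and 19 lower, 38 interferon genes). The type 17 helper cluster, led by CCR6, had 97 (73 and 24, 34 interferon genes). The cluster named memory, led by LMNA and LGALS1 with the type 2 helper genes GATA3 and PTGDR2, had 102 (77 and 25, 32 interferon genes). The proliferating cluster had 268 (122 and 146, 44 interferon genes). In the 22 libraries of the longer gene list these counts were 119, 11, 0 (edgeR, 929 at an unadjusted p under 0.05), 5 and 16, with 24, 2, 0, 1 and 3 interferon genes among them.

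Among single clusters, a naive-like cluster led by SOX4 held 6.71% of CD4+ T cells in healthy and 4.32% in SLE donors (permutation p adjusted over clusters 0.0411). The naive-like cluster led by TMIGD2 and FHIT held 17.95% and 13.2% (adjusted p = 0.0411), the one led by HRH2 4.67% and 3.20% (adjusted p = 0.0300) and the smaller regulatory-like cluster 1.74% and 2.95% (adjusted p = 0.0446). These are shares of all CD4+ T cells, and the whole classes moved the same way. Naive-like cells held 59.4% and 43.9%, and regulatory-like cells 7.62% and 13.01%. The cluster changes are therefore not separate from those of their classes. A cluster of 124 cells led by IFIT3, IFIT1 and RSAD2 and a cluster of 1527 cells led by CD79A and ZBTB16 took no name. They had 0 and 1 markers among their 10 leading genes.

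The series describes the healthy donors as matched, but the labels used here give no pairs. Between donors of the same number the correlation ranged from -0.164 to 0.820 with a median of 0.191, against a median of -0.111 between other numbers, and 6 of 10 pairs lay above 0.1. Of 10 healthy libraries, 3 matched best with their own number. The numbers were not taken to pair the donors, but a link between some donors of the same number stays open. Of 165 pairs of libraries of 1 group, 0 differed by no more than counting noise would give (lowest chi-square per degree of freedom 59.9).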
